A study of Homo sapiens with 12 samples.

How the data were processed

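Total RNA from 12 cultures of the lines 2102 EP and TCam-2, extracted with an RNeasy kit and converted to libraries with a Lexogen QuantSeq 3′ kit per the labels, was measured as gene-level counts. The deposited values are estimated counts per gene from Salmon 1.9.0, merged over the 12 libraries, and per the submitters' processing notes the tools also included Trim Galore, STAR 2.7.11b, R 4.2.0 and DESeq2, with GRCh38 as genome build. The order of these steps, the gene annotation and the handling of strand are not given in the sources used here. The table holds 63241 genes and 12 columns of counts, each column belonging to 1 library. Estimated counts need not be whole: a value more than 0.01 from a whole number marks reads that were shared between genes, and such genes are called uncertain below. Overlapping and antisense genes are uncertain too, since no use of strand is stated. The counts of short 3′ ends depend on where a transcript ends, and not on its length.

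The estimated counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3. Library sizes were scaled by TMM, genes with low counts were left out by filterByExpr with the 4 groups, and 15614 genes were tested. A single quasi-likelihood model (glmQLFit and glmQLFTest with robust estimation) with 4 group means was fitted to all 12 libraries, which leaves 8 residual degrees of freedom and a spread shared by the groups. The common biological coefficient of variation was 0.127. The 4 comparisons were I-BRD9 against DMSO in 2102 EP, the same in TCam-2, the difference between these effects (TCam-2 minus 2102 EP), and TCam-2 against 2102 EP with DMSO. P-values were adjusted by Benjamini and Hochberg within each comparison, and a gene was called at an adjusted p under 0.05. The ± beside a log2 fold change is its standard error from the model, and the ± beside a CPM value (counts scaled by library size and TMM) is the SD over 3 replicates. The labels call the replicates biological but do not say how the cultures were kept apart.

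Gene lists were written down with the comparisons, the tests and most alternatives before the data were examined. There were 32 lists, and each was tested with limma 3.58.1 (camera) on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, again with the correlation estimated from the data, and with fry, which asks whether a list's genes move 1 way on balance and does not compare them with other genes. Adjustment was over the lists within a comparison, and lists with fewer than 5 tested genes were left out of camera. The list of histone genes holds old and new symbols of the same genes, of which 16 were tested. Overlap of calls was tested with Fisher's exact test, and shares of counts with exact permutation tests, 2-sided, for which 3 against 3 libraries give no p below 0.1.

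The genes named in the text follow a rule. BRD9 and BRD7 come first. For each line the rule takes the 10 largest rises and the 10 largest falls among genes with a symbol (not an identifier, a clone, or a LINC, MIR, LOC, small nucleolar, Cajal body or antisense RNA symbol), an adjusted p under 0.05, all I-BRD9 libraries on 1 side of all DMSO libraries, and at least 10 CPM on average in the higher group. For the difference it takes the 5 most positive and the 5 most negative genes with an adjusted p under 0.05 and at least 10 CPM in the highest group, with the same symbols left out. The rule as fixed left out identifiers and clones only, and the script that applied it also left out the RNA symbols. From each list it takes up to 4 members per line with the largest changes past the threshold and all members of lists with fewer than 12 tested genes, and for the comparison with DMSO a set of 11 marker genes. The text prints values for part of these genes. Changes named outside the rule were not followed gene by gene through the alternatives. Some genes that the rule names are not reported here. HEXIM1, CCND1, TFCP2L1, members named to complete a count of 5 or fewer, other members named without a value, and genes named in the closing observations outside the rule were chosen after their values were seen.

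A fold change against a group with no counts is given as a bound over a floor of 3 counts over the group, and with 1 to 3 counts as a ratio with a 95% counting interval. Coordinates were taken from GENCODE release 29 on GRCh38, in which 58228 of the 63241 gene identifiers (92.1%) were found.

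The scripts were tested on simulated counts drawn from the real means and library sizes with 200 changed genes. The real comparisons called a far larger share of the genes tested. It was 36.8% in 2102 EP, 31.8% in TCam-2, 13.1% for the difference and 62.6% between the lines with DMSO. The adjusted p depends on that share, so the shares of recovered and of unchanged genes below need not hold for the real data. In the comparison of I-BRD9 with DMSO in 2102 EP (15260 genes tested), edgeR recovered 44.8% of the 1.5-fold, 65.7% of the 2-fold and 71.2% of the 4-fold changes, and in TCam-2 (15247 genes) 35.8%, 61.2% and 86.4%. For the difference between the lines (15236 genes) the shares were 7.5%, 56.7% and 75.8%, and for the lines with DMSO (15065 genes) 40.3%, 65.7% and 92.4%. Among the calls in these single draws, unchanged genes made up 8.3%, 8.3%, 6.1% and 7.7%, above the nominal level. Over 6 draws of the 2102 EP comparison they made up 4.7% of 774 calls, and 9.5% of 804 calls with a replicate block. In 4 draws with no changed gene the model without a block made 0 calls and the model with it made 22. The test of the block model was for this reason judged by its unadjusted p-values and not by its calls.

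The alternatives were RLE and upper-quartile scaling, mitochondrially encoded genes left out, no low-count filter, at least 5 CPM in 3 libraries, DESeq2 1.42.0, limma voom, a fit on only the 6 libraries compared, unrounded counts, blocks by replicate number or by library code, each library left out, and a log2 fold change of at least 1. Overlap of calls with each library left out, and list tests without members that had at most 3 counts in both groups of a line (of either line for the difference), were chosen after the data were seen. Every deposited column was used.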

Results

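Transcript abundance was measured in 2 human testicular germ cell tumour lines after exposure to I-BRD9. The line 2102 EP is an embryonal carcinoma line, a tumour type whose cells resemble pluripotent stem cells. TCam-2 is a seminoma line, a tumour type whose cells resemble primordial germ cells. I-BRD9 is a small molecule that binds the bromodomain of BRD9, a subunit of the non-canonical BAF (SWI/SNF) chromatin remodelling complex. Cells of each line were kept for 24 h in 15 µM I-BRD9 or in DMSO, the solvent, and each of the 4 groups comprised 3 libraries that the labels call biological replicates. 2102 EP was grown in DMEM and TCam-2 in RPMI medium. The library kit primes from the polyadenylated 3′ end of transcripts, so that counts report transcript ends. The series addresses BRD9 inhibition as a possible therapy for these tumours, and the comparisons below ask which transcripts changed in each line, whether the change differed between the lines, and how the lines differed in DMSO.

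The total estimated count per library was 8798611, 8680858 and 7924567 in 2102 EP with DMSO (replicates 1, 2 and 3), and 7290335, 9600293 and 8574882 with I-BRD9. In TCam-2 it was 8740075, 9837567 and 8506026 with DMSO, and 10053366, 8246626 and 8398056 with I-BRD9. Between 20850 and 22044 genes had a count in a library, and 15614 of 63241 genes passed the low-count filter. At this depth 3 counts corresponded to 0.298 to 0.412 CPM in a single library, and intervals and floors given for low counts cover counting error only. The first principal component held 67.4% of the variance and parted the lines, and the second held 13.2% and parted I-BRD9 from DMSO in both. Pearson r between replicates lay between 0.971 and 0.981. Replicates differed by more than sampling noise, with a chi-square per degree of freedom of 5.13 to 13.5, so that no library was a second sequencing of another. Whether the libraries came from separate cultures cannot be told from these values.

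BRD9 (ENSG00000028310, chromosome 5, 850291 to 892824, minus strand, GRCh38) was transcribed in every group. Its level was 111.0 ± 11.7 CPM (SD, n = 3) with DMSO and 92.6 ± 11.2 with I-BRD9 in 2102 EP, a log2 fold change of −0.26 ± 0.09 (SE; edgeR adjusted p = 0.0328). That call was lost without I-BRD9 replicate 2 (adjusted p = 0.105), I-BRD9 replicate 3 (0.166), DMSO replicate 1 (0.0645) or DMSO replicate 3 (0.177), and with upper-quartile scaling (0.0712), a library-code block (0.0555) or a fit on the 6 libraries of the line (0.0741). In TCam-2 BRD9 had 141.8 ± 3.62 CPM with DMSO and 122.9 ± 6.88 with I-BRD9 (log2 fold change −0.21 ± 0.09, edgeR adjusted p = 0.0965, and 0.0335 in a fit on the 6 libraries of the line). BRD7 (ENSG00000166164, chromosome 16, 50313487 to 50368934, minus strand), the related bromodomain gene of another BAF assembly, had log2 fold changes of −0.03 (edgeR adjusted p = 0.77) in 2102 EP and 0.02 (0.906) in TCam-2, with reads shared between genes in every library. The compound acts on the protein, so these levels do not measure its inhibition.

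In 2102 EP, 26 of the 28 pluripotency genes tested fell after I-BRD9. GDF3 (ENSG00000184344, chromosome 12, 7689782 to 7695776, minus strand), a growth factor gene of pluripotent cells, fell from 420.2 ± 48.6 to 22.2 ± 7.10 CPM (SD, n = 3). NANOG (ENSG00000111704, chromosome 12, 7787794 to 7799141, plus strand), a core pluripotency factor gene, fell from 175.3 ± 19.4 to 19.3 ± 1.40 CPM. CDX2 (ENSG00000165556, chromosome 13, 27962137 to 27971139, minus strand), a transcription factor gene of trophoblast and hindgut, rose from 0.283 ± 0.0874 to 16.3 ± 3.05 CPM, and HAND1 (ENSG00000113196, chromosome 5, 154474972 to 154478264, minus strand), a factor of mesoderm and trophoblast, from 5.31 ± 0.719 to 73.6 ± 6.07 CPM. By edgeR's quasi-likelihood test 2837 genes rose and 2902 fell, together 36.8% of the genes tested, and 1076 of the rises and 865 of the falls were at least 2-fold.

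Genes were ranked among those called, with separated groups and at least 10 CPM in the higher group, leaving out identifiers, clones and LINC, MIR, small nucleolar, Cajal body and antisense RNA symbols. The largest rises in 2102 EP within these limits were those of CDX2 (log2 fold change 5.79 ± 0.50, SE), ZEB2 (4.30 ± 0.47) and MSX1 (4.23 ± 0.44), followed by CGREF1, UCA1, ANKRD1, HAND1, RTL5, WLS and AHNAK2, the last at 3.48 ± 0.44. The largest falls within these limits were those of C19orf85 (−5.39 ± 0.39), DELEC1 (−4.84 ± 0.39), LEFTY2 (−4.58 ± 0.14) and HAS3 (−4.47 ± 0.53), followed by DPPA3, VENTX, GDF3, FGF19, GLIPR1L1 and IL23A, the last at −3.93 ± 0.27. The edgeR adjusted p of these 20 genes was at most 2.68e-05, that of DPPA3, a gene with shared reads in part of the libraries. In all 20, every I-BRD9 library lay on one side of every DMSO library, a condition of the rule that chose them. Among all tested genes 46.3% were separated in this way, against 10% by chance, and 5446 of the called genes were.

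Of the 28 pluripotency genes, 26 fell in 2102 EP, TFCP2L1 rose (log2 fold change 0.35 ± 0.10, edgeR adjusted p = 0.0107) and TRIM71 (−0.13) did not pass (camera adjusted p = 1.27e-17; median log2 fold change −2.11). The rise of TFCP2L1 was lost without DMSO replicate 1, where no member was called higher. LEFTY2, a NODAL antagonist gene, fell from 242.6 ± 23.0 CPM by 4.58 ± 0.14 on the log2 scale, and DPPA3 from 130.5 ± 34.5 to 5.90 ± 3.20. FOXD3 had 1 count over the 3 I-BRD9 libraries, and its level with DMSO was 35.8 times as high (95% counting interval 5.80 to 1410). POU5F1, whose pseudogenes share its reads, fell by 1.05 on the log2 scale and SOX2 by 0.87. Of 13 seminoma and primordial germ cell genes, 5 fell (DND1, LHX8, PRDM1, SOX15 and ALPL) and CXCR4 rose (1.85 ± 0.29, edgeR adjusted p = 8.46e-06). DND1, a germ cell RNA-binding protein gene, changed most (−2.94 ± 0.30), and PRDM1 shared reads with other genes. The camera test of this list was past the threshold (adjusted p = 0.0192), which it did not pass with an estimated correlation (adjusted p = 0.199 with an estimated correlation). Its members SOX17 and PRAME had at most 3 counts in both groups, so that their response in 2102 EP could not be measured. For every list, the numbers of calls adjusted over the list alone were those adjusted over all genes unless another number is given.

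**Figure D1:**
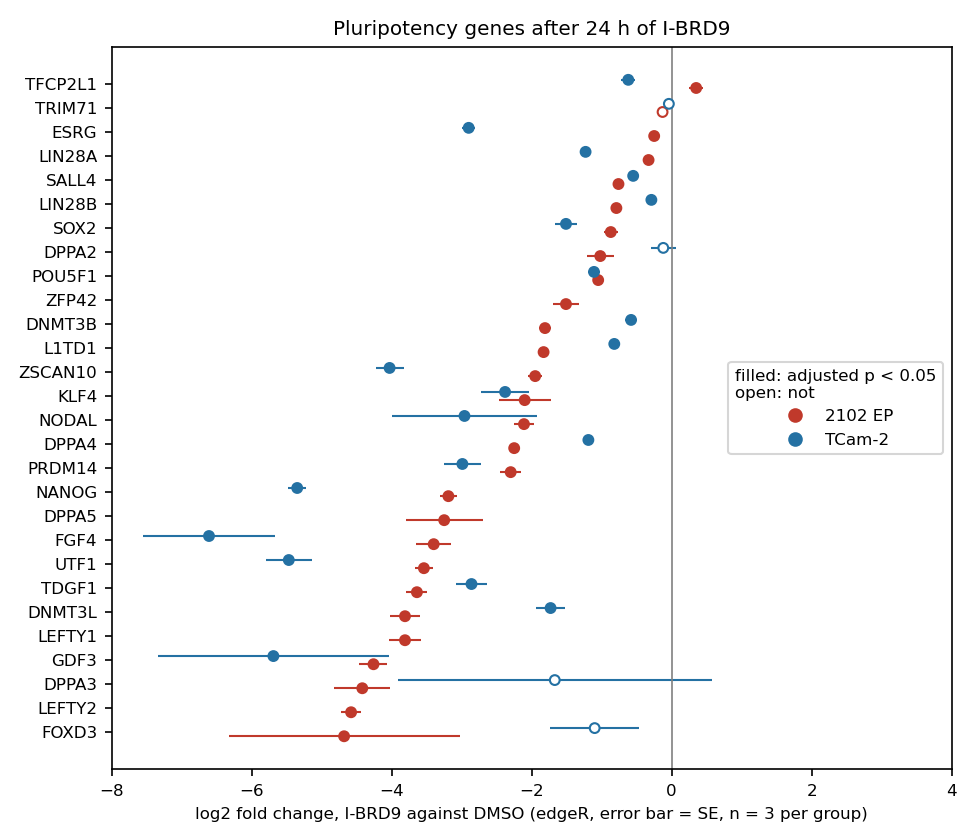
Log2 fold change with I-BRD9 against DMSO (x axis) of the 28 pluripotency genes (y axis) in 2102 EP (red) and TCam-2 (blue), with the SE as bar (n = 3 per group) and filled points where the edgeR adjusted p was under 0.05. In 2102 EP 26 genes fell and in TCam-2 20; ZFP42, DPPA5, LEFTY1 and LEFTY2 are not drawn for TCam-2, where at least 1 group had no count or both were at or under 3 counts.

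Lineage lists in 2102 EP held rises and falls side by side. Of 9 trophoblast genes CDX2, GATA2 (1.35 ± 0.19) and GATA3 (0.58 ± 0.11) rose and KRT7 fell (−0.60, edgeR adjusted p = 0.0119), a call lost without I-BRD9 replicate 3 (0.102) or DMSO replicate 1 (0.0798), with limma voom (0.0653) and in a fit on the 6 libraries of the line (0.0932). The list did not pass camera (adjusted p = 0.236): its median was 0 and its mean 0.80, and 4 members had at most 3 counts in both groups. Of 9 mesoderm genes MSX1, HAND1 and MSX2 rose and PDGFRA (−3.12 ± 0.64), WNT3 (−2.68 ± 0.22) and MIXL1 fell (3 rose and 4 fell adjusted over the list alone; median −0.50, camera direction up, adjusted p = 0.877). MIXL1 (−0.75, edgeR adjusted p = 0.0278) was lost without I-BRD9 replicate 2 (0.0674), I-BRD9 replicate 3 (0.113), DMSO replicate 1 (0.0792) or DMSO replicate 3 (0.165), and with a library-code block (0.0649). Of 9 neuroectoderm genes, 5 rose and ZIC2 fell (5 and 2 adjusted over the list alone; camera adjusted p = 0.0885). MAP2, a neuronal cytoskeleton gene with no count in the DMSO libraries, rose at least 22.7-fold over a floor of 3 counts over the group. NCAM1 rose by 2.31 ± 0.29 and TUBB3, with shared reads, by 2.26 ± 0.10 on the log2 scale, and NES and GAP43 rose by less. The GAP43 call (0.50, edgeR adjusted p = 0.0297) was lost without I-BRD9 replicate 1 (0.0585), I-BRD9 replicate 2 (0.103) or DMSO replicate 1 (0.161).

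Of 7 endoderm and yolk sac genes in 2102 EP, GATA6 (2.46 ± 0.68) and SOX7 rose, and GATA4 (−2.37 ± 0.69), CER1 (−2.30 ± 0.60) and DUSP4 fell (median 0.08, mean −0.24, camera adjusted p = 0.511). The SOX7 call (1.21, edgeR adjusted p = 0.0408) was lost without I-BRD9 replicate 1 (0.133) or 2 (0.105) and without DMSO replicate 1 (0.145), 2 (0.0764) or 3 (0.064). It was also lost with limma voom (0.0841), a replicate block (0.0656) or a library-code block (0.0765). Of 26 extracellular matrix and mesenchymal transition genes 9 rose and 5 fell (10 and 6 adjusted over the list alone; camera adjusted p = 0.138). ZEB2, TWIST1 (2.66 ± 0.31) and ZEB1 (2.30 ± 0.57), transcription factor genes of the mesenchymal state, and TGFBI (2.36 ± 0.22) rose most, and the collagen IV genes COL4A2 (−1.32) and COL4A1 (−1.07) fell with MMP9 and ITGB1 among others. Of 5 fibroblast and stromal genes THY1 (−0.89 ± 0.09) and COL1A2 fell (1 rose and 3 fell adjusted over the list alone; camera adjusted p = 0.407), and 1 member rose without DMSO replicate 3. The COL1A2 call (−1.32, edgeR adjusted p = 0.0132) was lost without I-BRD9 replicate 1 (0.0694) or 2 (0.0706) and with limma voom (0.136). Of the 2 blood and immune genes tested CD68 rose from 0.698 ± 0.507 to 2.95 ± 1.02 CPM, and 1 member fell without I-BRD9 replicate 1 or 3 or DMSO replicate 2. Of 5 testis somatic genes SOX9 rose (0.89 ± 0.18) and GATA4 fell (median −0.08, camera direction up, adjusted p = 0.927).

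Cell cycle genes fell in 2102 EP. Of 25 G2/M and mitosis genes 23 fell and none rose (camera adjusted p = 1.12e-09; median −0.53), led by HMMR (−1.35 ± 0.08), KIF20A (−1.28 ± 0.14) and UBE2C (−0.97 ± 0.09). Of 25 G1/S and DNA replication genes 20 fell and none rose (21 fell adjusted over the list alone; camera adjusted p = 9.69e-06; median −0.39), among them MCM2 (−1.25 ± 0.24) and MCM5 (−1.20 ± 0.10), subunits of the replicative helicase. Of 20 MYC targets 7 fell and none rose (9 fell adjusted over the list alone), with NOP16 at −0.85 ± 0.13 and WDR12 at −0.61 ± 0.10 (camera adjusted p = 0.0121; adjusted p = 0.052 with an estimated correlation). Of 25 p53 targets 9 rose and 4 fell (camera adjusted p = 0.497). BTG2 (2.56 ± 0.28), TP53INP1 (1.45 ± 0.22) and CDKN1A (1.12 ± 0.14), an inhibitor of cyclin-dependent kinases, rose, and GDF15 (−1.59 ± 0.12), AEN, BBC3 and MDM2 fell. Of 26 apoptosis regulators 5 rose and 8 fell (median above 0, mean −0.03, camera direction down, adjusted p = 0.511), with 3 rises without I-BRD9 replicate 1 or without DMSO replicate 1. The list holds inhibitors and promoters of apoptosis, so a test for a shift in 1 direction cannot tell whether the pathway changed. CFLAR, an inhibitor of caspase-8 activation, fell (−2.05 ± 0.10) as did PMAIP1 (−1.03 ± 0.11), and BMF (1.53 ± 0.41), HRK, BIK and APAF1 were among those that rose.

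Stress and metabolic lists in 2102 EP moved in both directions. Of 26 integrated stress response genes 16 fell and 4 rose (18 and 4 adjusted over the list alone; camera adjusted p = 5e-05; median −0.49). CHAC1 fell from 63.2 ± 5.03 to 4.92 ± 1.30 CPM, SLC7A11 (−2.92 ± 0.19) and STC2 (−2.36 ± 0.11) fell, while SLC7A5, ATF3, SARS1 and SLC3A2 rose. Of 19 endoplasmic reticulum chaperone and unfolded protein response genes 13 fell (camera adjusted p = 0.000316), with XBP1 at −1.27 ± 0.10 and HERPUD1 at −0.87 ± 0.16. Of 25 cholesterol synthesis genes 14 rose and 1 fell (camera adjusted p = 0.000646; adjusted p = 0.0772 with an estimated correlation), and 2 members fell without I-BRD9 replicate 3. INSIG1 rose from 50.9 ± 5.62 to 262.9 ± 31.2 CPM, TM7SF2 by 2.10 ± 0.13 and MVD by 1.30 ± 0.21 on the log2 scale. Of 23 lysosome genes 12 rose and none fell (camera adjusted p = 0.000714), with SQSTM1 at 1.69 ± 0.09 and NPC2 at 1.10 ± 0.09; 1 member fell without I-BRD9 replicate 3. Of 19 immediate early genes 13 rose and 3 fell (14 and 3 adjusted over the list alone; camera adjusted p = 0.000217; median 0.82). FOSB (2.28 ± 0.30) and DUSP1 (1.62 ± 0.24) rose, KLF2, with 3 counts over the DMSO libraries, was 9.40 times as high (95% counting interval 2.86 to 47.3), and KLF4, FOSL1 and DUSP6 fell.

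Of 8 metallothionein genes 6 fell in 2102 EP and none rose (camera adjusted p = 0.00193; adjusted p = 0.221 with an estimated correlation). MT1X fell by 1.19 ± 0.19 and MT1F by 0.69 ± 0.07 on the log2 scale, and MT1H, MT1M and MT1G, whose near-identical copies share reads, fell too. The call of MT1E (−0.86, edgeR adjusted p = 0.0219) was lost without DMSO replicate 1 (0.0698) or 2 (0.0839), with no low-count filter (0.055) and in a fit on the 6 libraries of the line (0.118). Of 13 heat shock genes HSPA4L and DNAJB1 rose and 5 fell (3 and 6 adjusted over the list alone; camera adjusted p = 0.411), with HSPB1 at −0.82 ± 0.08. Of 19 NRF2 targets 3 rose and 3 fell (median 0.02, mean −0.09, camera direction down, adjusted p = 0.773), with 5 rises without I-BRD9 replicate 2. FTL, ferritin light chain, rose (1.48 ± 0.07) with PGD and TXNRD1, and SLC7A11, PIR and NQO1 fell. Of 4 aryl hydrocarbon receptor targets, too few for a list test, TIPARP (1.86 ± 0.24) and CYP1B1 (0.73 ± 0.12) rose and NQO1 fell (3 rose adjusted over the list alone). Of 27 glycolysis and hypoxia genes 10 rose and 9 fell (11 and 9 adjusted over the list alone; camera adjusted p = 0.497). SLC2A3, a glucose transporter gene with shared reads, rose from 489.5 ± 9.09 to 2303 ± 86.1 CPM and ADM by 1.47 ± 0.16 on the log2 scale.

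Of 24 interferon-stimulated genes 5 rose and 4 fell in 2102 EP (7 and 4 adjusted over the list alone; camera adjusted p = 0.296), with 3 rises without I-BRD9 replicate 3. B2M, the light chain of MHC class I, rose from 100.9 ± 3.56 to 244.2 ± 26.7 CPM with IRF7 and IRF1 among others, and BST2 (−2.60 ± 0.25) and IFITM1, IFITM2 and IFITM3 fell. Of 9 NF-kB targets TNF, IER3 (0.82 ± 0.09) and RELB rose and CCL2 fell (camera adjusted p = 0.345). TNF had 1 count over the DMSO libraries and a ratio of 28.2 (95% counting interval 5.09 to 1240). The RELB call (0.57, edgeR adjusted p = 0.0162) was lost without I-BRD9 replicate 1 (0.103) or DMSO replicate 2 (0.0806). Of 16 replication-independent and polyadenylated histone genes 7 rose and H2AZ1 fell (7 and 2 adjusted over the list alone; camera adjusted p = 0.0611), led by H2BC5 (1.63 ± 0.17) and H2BC21 (1.49 ± 0.31, shared reads); 2 members fell without I-BRD9 replicate 1.

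Of 29 BAF complex genes 4 rose and 11 fell in 2102 EP (camera adjusted p = 0.0612). BCL11B (−1.67 ± 0.18), DPF1 (−1.57 ± 0.13) and PHF10 (−1.07 ± 0.19) fell, and DPF3 (shared reads), SMARCD3, SMARCB1 and PBRM1 rose. The number of falls was 6 without I-BRD9 replicate 3, and that of rises 2 without DMSO replicate 2. A list of BET bromodomain genes and genes that respond to BET inhibitors was included because I-BRD9 is a bromodomain ligand. Of its 16 genes 5 rose (SERPINI1, ZCCHC24, HEXIM1, CCND1 and BRD2) and 5 fell (MYCN, ZMYND8, E2F2, FOSL1 and BRD3), and 7 and 6 did adjusted over the list alone (camera adjusted p = 0.819). The list was not sorted by the direction in which BET inhibitors move its genes. Camera tests for a shift in 1 direction, so it cannot tell whether a BET response was present. SERPINI1 rose by 1.73 ± 0.32 and ZCCHC24 by 1.69 ± 0.20, and ZMYND8 (−1.47 ± 0.08) and MYCN (−1.69 ± 0.14) fell. HEXIM1, a gene widely used as a marker of BET inhibition and chosen here after its values were seen, rose by 1.20 ± 0.10. Mitochondrially encoded transcripts took 11.2 ± 0.317% of the counts with I-BRD9 and 9.19 ± 0.949% with DMSO (exact permutation p = 0.1, 2-sided, the smallest that 3 against 3 libraries allow). Of these 13 genes 6 rose (camera adjusted p = 0.0354; adjusted p = 0.37 with an estimated correlation), with MT-ND6 at 1.35 ± 0.10 and MT-ND1 at 0.64 ± 0.09. Of 37 cytosolic ribosomal protein genes 9 fell, and 3 did adjusted over the list alone (camera adjusted p = 0.0462; adjusted p = 0.539 with an estimated correlation). The number that fell was 5 without I-BRD9 replicate 1, 5 without DMSO replicate 1 and 3 without DMSO replicate 2, where 1 rose, and it was 4 with upper-quartile scaling.

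The 2102 EP test rested on 3 libraries per group and a spread pooled over the 4 groups. With estimated correlations the calls of the pluripotency, G1/S, G2/M, integrated stress response, endoplasmic reticulum, immediate early and lysosome lists held.

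In TCam-2, 20 of the 28 pluripotency genes tested fell after I-BRD9. NANOG fell from 524.5 ± 29.8 to 12.8 ± 3.20 CPM (SD, n = 3). CXCR4 (ENSG00000121966, chromosome 2, 136114349 to 136118165, minus strand), a chemokine receptor gene of migrating germ cells, fell from 129.2 ± 3.17 to 3.90 ± 0.369 CPM, and SOX17 (ENSG00000164736, chromosome 8, 54457935 to 54460888, plus strand), a factor of seminoma and primordial germ cells, from 192.8 ± 6.66 to 45.3 ± 3.12. CDKN1C (ENSG00000129757, chromosome 11, 2883213 to 2885773, minus strand), which encodes the cyclin-dependent kinase inhibitor p57, rose from 11.3 ± 2.14 CPM by 3.14 ± 0.12 on the log2 scale. By edgeR's quasi-likelihood test 2389 genes rose and 2570 fell, together 31.8% of the genes tested, and 732 of the rises and 791 of the falls were at least 2-fold.

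The largest rises in TCam-2, within the limits used for 2102 EP (called, separated groups, at least 10 CPM in the higher group, the same symbols left out), were those of H4C14 (log2 fold change 3.27 ± 0.72, SE), H4C15 (3.15 ± 0.22), CDKN1C and H2BC5 (2.81 ± 0.18), followed by NEAT1, H2BC21, DUSP1, KIF1A, BEX5 and WIPI1, the last at 2.20 ± 0.23. H4C14, H4C15, H2BC21 and NEAT1 had reads shared between genes, so their values are uncertain. The kit primes from polyadenylated ends, so the values of the histone genes cover only their polyadenylated transcripts. Histone transcripts without such ends were not counted. The largest falls within these limits were those of DIO3, GFRA1 (−5.98 ± 0.61), UTF1 (−5.47 ± 0.33), NANOG (−5.35 ± 0.13), RNASE1 (−5.20 ± 0.73) and CXCR4 (−5.05 ± 0.17), followed by ANGPTL4, CD38, ETV4 and ASIC2, the last at −4.46 ± 0.42. DIO3, a thyroid hormone deiodinase gene, had 3 counts over the I-BRD9 libraries, and its level with DMSO was 150 times as high (95% counting interval 51.5 to 738). The edgeR adjusted p of these 20 genes was at most 0.00628, that of H4C14. Among all tested genes 45.7% had fully separated groups, against 10% by chance, and 4822 of the called genes did.

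**Figure D2:**
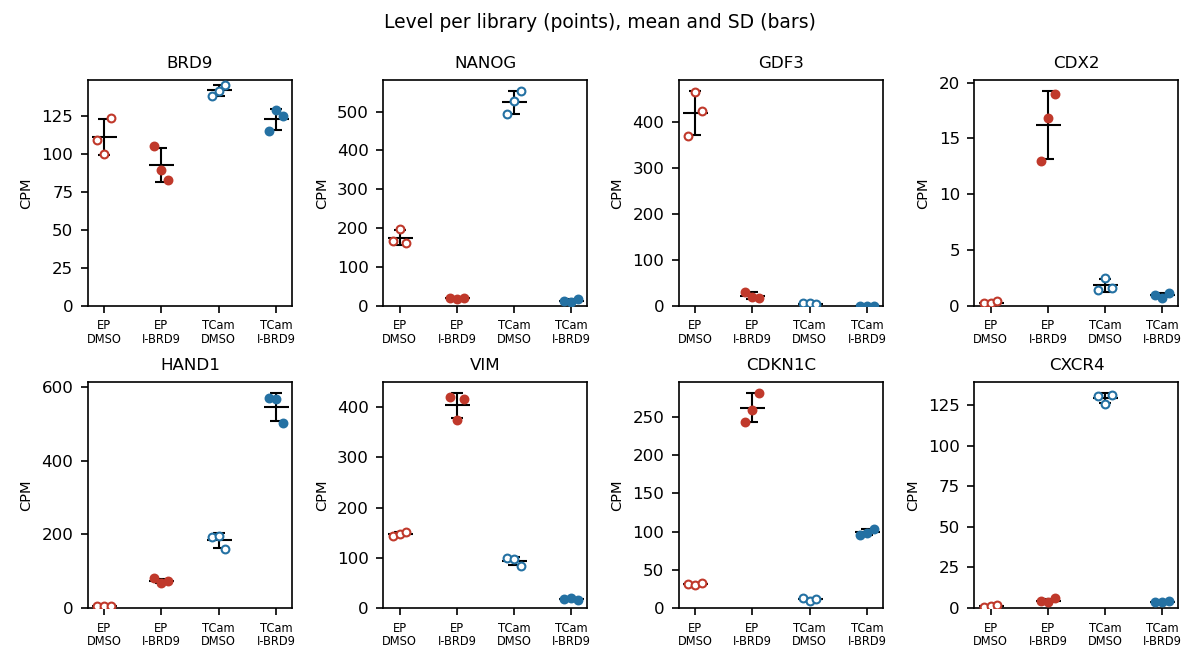
Abundance in CPM (y axes, from 0) of 8 genes in the 4 groups (x axis: 2102 EP in red, TCam-2 in blue, open points DMSO, filled points I-BRD9), each point a library and the black bar the mean with SD (n = 3). NANOG and GDF3 are lower with I-BRD9 in both lines, CDKN1C and HAND1 are higher in both, and CXCR4 and VIM go in opposite directions.

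Of the 28 pluripotency genes, 20 fell in TCam-2 and none rose (21 fell adjusted over the list alone; camera adjusted p = 2.64e-14; median −1.59, and −1.67 over the 25 members with more than 3 counts in a group). FGF4 had 2 counts over the I-BRD9 libraries and a level 112 times as high with DMSO (95% counting interval 32.1 to 975), and for GDF3, also with 2 counts, the ratio was 57.5 (16.7 to 516). UTF1 fell from 31.7 ± 2.80 to 0.686 ± 0.322 CPM, ZSCAN10 by 4.03 on the log2 scale and POU5F1, with shared reads, by 1.11. Of 13 seminoma and primordial germ cell genes 8 fell and KIT rose (0.90 ± 0.16), and LHX8 had at most 3 counts in both groups. CXCR4, CD38 (−4.58 ± 0.77), PRDM1 (−2.40 ± 0.24, shared reads) and SOX17 (−2.09 ± 0.09) fell most (camera adjusted p = 0.000862; adjusted p = 0.0707 with an estimated correlation). TFAP2C, another factor of this state, had a log2 fold change of −0.28 (edgeR adjusted p = 0.342).

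Of 25 G2/M and mitosis genes all 25 fell in TCam-2 (camera adjusted p = 4.93e-13; median −0.61), led by UBE2C (−1.10 ± 0.09), PLK1 (−1.03 ± 0.09) and AURKA (−0.99 ± 0.08, shared reads). Of 25 G1/S and DNA replication genes 22 fell and none rose (camera adjusted p = 1.63e-10; median −0.64), with CDC45 at −0.95 ± 0.22, MCM5 at −0.92 ± 0.11 and CCNE2 at −0.91 ± 0.22. The call of MCM2 (−0.89, edgeR adjusted p = 0.0196) was lost without I-BRD9 replicate 1 (0.0706) or 2 (0.0653) or DMSO replicate 3 (0.0716), and with no low-count filter (0.0543). Of 20 MYC targets 14 fell and none rose (16 fell adjusted over the list alone; camera adjusted p = 1.44e-06), led by NOP16 (−0.89 ± 0.13) and RRP9 (−0.87 ± 0.10), both genes of ribosome assembly. Of 25 p53 targets 6 rose and 10 fell (6 and 12 adjusted over the list alone; camera adjusted p = 0.0569). TP53INP1 (1.32 ± 0.16) rose, and GDF15 (−1.78 ± 0.20), AEN (−1.32 ± 0.09) and PHLDA3 (−1.28 ± 0.10) fell. Of 26 apoptosis regulators 3 rose and 6 fell (4 and 7 adjusted over the list alone; camera adjusted p = 0.459). CASP8, the initiator caspase of death receptors, fell (−2.28 ± 0.14) together with its inhibitor CFLAR (−1.74 ± 0.09), and BMF (1.84 ± 0.30), BCL2L11 and BBC3 rose. The call of BCL2L11 (0.85, edgeR adjusted p = 0.017) was lost without I-BRD9 replicate 1 (0.0892) or DMSO replicate 2 (0.0913) or 3 (0.0821).

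Of 25 cholesterol synthesis genes 19 rose in TCam-2 and 1 fell (21 and 1 adjusted over the list alone; camera adjusted p = 1.1e-08), with TM7SF2 at 1.59 ± 0.11, INSIG1 at 1.52 ± 0.11 and LSS at 1.35 ± 0.13. Of 23 lysosome genes 10 rose and none fell (camera adjusted p = 0.00754), led by SQSTM1 (0.82 ± 0.09). Of 19 immediate early genes 11 rose and 3 fell (12 and 3 adjusted over the list alone; camera adjusted p = 0.000367; median 0.86). DUSP1 (2.47 ± 0.23) and JUN (1.64 ± 0.10) rose, and KLF4 (−2.38 ± 0.34), DUSP6 (−2.22 ± 0.44) and IER3 fell. Of 26 integrated stress response genes 14 fell and 4 rose (camera adjusted p = 0.00178; adjusted p = 0.0589 with an estimated correlation). WARS1 (−1.75 ± 0.08), STC2 (−1.71 ± 0.11) and CTH (−1.18 ± 0.22) fell, and SLC7A5, ATF3, SLC3A2 and ASNS rose. Of 19 endoplasmic reticulum genes 8 fell and SEL1L rose, with XBP1 at −0.78 ± 0.11 and CRELD2 at −0.77 ± 0.12 (camera adjusted p = 0.0302; adjusted p = 0.0707 with an estimated correlation). Of 13 heat shock genes 6 fell and none rose, led by HSPB1 (−1.43 ± 0.08; camera adjusted p = 0.028; adjusted p = 0.0707 with an estimated correlation). Of 8 metallothioneins 7 fell, all but MT2A (camera adjusted p = 4.17e-07; adjusted p = 0.0681 with an estimated correlation). MT1X fell by 2.51 ± 0.23 and MT1E by 1.82 ± 0.24 on the log2 scale, and MT1M, MT1G and MT1H have shared reads.

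Of 19 NRF2 targets 6 rose and 3 fell in TCam-2 (6 and 4 adjusted over the list alone; camera adjusted p = 0.167), with FTL at 1.33 ± 0.08, TXNRD1 at 0.76 ± 0.11 and ABCC2 at −1.86 ± 0.41. Of 4 aryl hydrocarbon receptor targets TIPARP (1.25 ± 0.20) and CYP1B1 (1.23 ± 0.09) rose (3 rose and 1 fell adjusted over the list alone), and NQO1 had a log2 fold change of −0.21 (edgeR adjusted p = 0.0504). NQO1 passed without DMSO replicate 3 (0.0301), with mitochondrially encoded genes left out (0.0395), with limma voom (0.0376) or DESeq2 (0.0483), and in a fit on the 6 libraries of the line (0.0267). Of 27 glycolysis and hypoxia genes 7 rose and 10 fell (9 and 13 adjusted over the list alone; camera adjusted p = 0.484), with 4 rises without I-BRD9 replicate 2 or DMSO replicate 2 or 3. The list's median was 0.08, its mean −0.08 and the direction of its test down. EGLN3 (−1.22 ± 0.22) fell and BNIP3L (1.05 ± 0.11) rose. Of 24 interferon-stimulated genes 4 rose and 4 fell (4 and 5 adjusted over the list alone; median −0.23, camera direction up, adjusted p = 0.961). B2M rose from 7.35 ± 0.95 to 30.9 ± 0.80 CPM, with IRF1 among others. IFITM3, IFIT1, MX1 and ISG20 fell, and 2 members fell without I-BRD9 replicate 2 or 3 or DMSO replicate 2. ISG20 was lost without any 1 of the 6 libraries of the line (edgeR adjusted p 0.0573 to 0.115), with no low-count filter (0.0706) and with DESeq2 (0.0564), and MX1 without DMSO replicate 1 (0.065). IFIT1, with no count in the I-BRD9 libraries, was lost when any 1 I-BRD9 replicate (0.0638 to 0.0737) or DMSO replicate 2 (0.135) was left out, and with a replicate block (0.0674), a library-code block (0.0602) or limma voom (0.0685). Of 9 NF-kB targets TNF and RELB (1.35 ± 0.27) rose and CCL2 (−2.75 ± 0.49), NFKB2 (−1.24 ± 0.19) and IER3 (−1.10 ± 0.09) fell (camera adjusted p = 0.445), and TNF had a ratio of 12.2 over 3 DMSO counts (95% counting interval 3.98 to 63.3). Of 16 histone genes 5 rose and H1-2 and H2AZ1 fell (6 and 2 adjusted over the list alone). H2AC6 (2.86 ± 0.31) and H2BC5 rose, and the list had a median of −0.06, a mean of 0.47 and an upward camera direction (adjusted p = 0.218).

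Of 26 extracellular matrix and mesenchymal transition genes 4 rose and 7 fell in TCam-2 (5 and 7 adjusted over the list alone; camera adjusted p = 0.345). VIM, which encodes the intermediate filament vimentin, fell from 93.9 ± 8.25 to 17.7 ± 2.25 CPM, CDH2 by 1.89 ± 0.09 and MMP2 by 1.89 ± 0.26 on the log2 scale, and TWIST1, TGFBI and LAMB1 were among those that rose. Of 5 fibroblast and stromal genes THY1 (−3.65 ± 0.21) and COL1A2 (−0.69 ± 0.13) fell (camera adjusted p = 0.0522). Of 9 trophoblast genes GATA2 (1.27 ± 0.16) and GATA3 (0.58 ± 0.09) rose and TP63 (−3.29 ± 0.68), CGA, KRT7 (−1.22 ± 0.10), VGLL1 and CDX2 fell (camera adjusted p = 0.0932), and 3 fell with DESeq2. The call of CGA (−3.10, edgeR adjusted p = 0.00268) was lost with DESeq2 (0.0878). The CDX2 call (−0.92, edgeR adjusted p = 0.0483) was lost with DESeq2 (0.0878), limma voom (0.152), upper-quartile scaling (0.0562), no low-count filter (0.103), a replicate block (0.0744), a library-code block (0.0517) or a fit on the 6 libraries of the line (0.113). It was also lost without I-BRD9 replicate 1 (0.0979), 2 (0.157) or 3 (0.0542) or DMSO replicate 2 (0.248) or 3 (0.0572). Of 9 neuroectoderm genes TUBB3 (2.08 ± 0.10, shared reads), ZIC1 (1.79 ± 0.13), NCAM1 and NES rose and ZIC2, OTX2 (−2.76 ± 0.27), SIX3 and GAP43 fell (5 and 4 adjusted over the list alone). This list had a median of 1.11, a mean of −0.08 and an upward camera direction (adjusted p = 0.459). GAP43 (−0.83) was lost without I-BRD9 replicate 1 (edgeR adjusted p = 0.0637), and ZIC2, with 1 count over the I-BRD9 libraries, without I-BRD9 replicate 2 (0.0815) or 3 (0.0811) or DMSO replicate 1 (0.102) or 3 (0.0999), and with limma voom (0.203).

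Of 9 mesoderm genes HAND1 rose in TCam-2 by 1.58 ± 0.09 on the log2 scale, to 546.7 ± 38.1 CPM, and HAND2 (−1.96 ± 0.47), MSX2 (−0.45 ± 0.10), TBX5 and MSX1 fell (camera adjusted p = 0.459). MSX1 (−1.44) was lost without I-BRD9 replicate 2 (edgeR adjusted p = 0.0716) or DMSO replicate 1 (0.0734), and with limma voom (0.0787). TBX5 (−1.80) was lost without I-BRD9 replicate 1 (0.0951) or 3 (0.123) or DMSO replicate 1 (0.237) or 2 (0.0574), and with limma voom (0.0622). Of 7 endoderm and yolk sac genes GATA6 rose and DUSP4 (−2.38 ± 0.22) and GATA4 (−1.38 ± 0.33) fell (2 and 2 adjusted over the list alone; camera adjusted p = 0.562). GATA6 (1.17) was lost without I-BRD9 replicate 3 (edgeR adjusted p = 0.0533) or DMSO replicate 3 (0.0541), and SOX7 (1.10, 0.0502) was called without DMSO replicate 2 (0.0162), with upper-quartile scaling (0.0447), no low-count filter (0.0195), a replicate block (0.0453) or limma voom (0.0228), and in a fit on the 6 libraries of the line (0.0431). Neither of the 2 blood and immune genes passed, with an edgeR adjusted p of 0.821 for CD68. Of 5 testis somatic genes GATA4 and CLDN11 fell (camera adjusted p = 0.459). CLDN11 (−1.77) was lost without I-BRD9 replicate 2 (0.0655) or 3 (0.0755) or DMSO replicate 1 (0.122) or 2 (0.0638).

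Of 29 BAF complex genes 5 rose and 5 fell in TCam-2 (camera adjusted p = 0.285). SMARCD3 (3.05 ± 0.60), SMARCA2 (0.66 ± 0.11), BCL11A, PBRM1 and SMARCE1 rose, and BCL11B (−2.79 ± 0.12), DPF1, BCL7A, ARID1A and ARID1B fell. The number of rises was 2 without I-BRD9 replicate 1 or 2 or DMSO replicate 1, and 3 without DMSO replicate 3. Of 16 BET-related genes 5 rose (ZCCHC24, SERPINI1, HEXIM1, BRD2 and BRD3) and 5 fell (CCND2, ZMYND8, E2F2, MYCN and CCND1; camera adjusted p = 0.85), with ZCCHC24 at 2.63 ± 0.31, CCND2 at −1.62 ± 0.08 and ZMYND8 at −1.27 ± 0.08. HEXIM1 rose by 0.93 ± 0.10. The list's median was 0.03 and its mean −0.07. The mitochondrially encoded share was 6.97 ± 0.852% with I-BRD9 and 7.23 ± 0.190% with DMSO (exact permutation p = 0.8, 2-sided). MT-ATP6 (−0.39 ± 0.10, shared reads) and MT-CYB fell among the 13 mitochondrially encoded genes (1 fell adjusted over the list alone; camera adjusted p = 0.0562). MT-CYB (−0.27) was lost without I-BRD9 replicate 1 (edgeR adjusted p = 0.132) or 2 (0.119) or DMSO replicate 3 (0.354), with upper-quartile scaling (0.0773), a filter of 5 CPM in 3 libraries (0.0523) or limma voom (0.0562), and in a fit on the 6 libraries of the line (0.0769). Of 37 ribosomal protein genes RPL6, RPL32 and RPS14 fell, and none did adjusted over the list alone (camera adjusted p = 0.055). RPL6 was lost without I-BRD9 replicate 2 (edgeR adjusted p = 0.0662), I-BRD9 replicate 3 (0.0541) or DMSO replicate 3 (0.0546). RPL32 was lost without I-BRD9 replicate 1 (0.065) or 3 (0.0647) or DMSO replicate 2 (0.0623) or 3 (0.0501), and RPS14 without any 1 of the 6 libraries (0.0535 to 0.109). The list had no member called lower without I-BRD9 replicate 3 and, over the other settings, 1 to 9. RPL32 and RPS14 were also lost with upper-quartile scaling (0.0549 and 0.0693) and with no low-count filter (0.0852 and 0.0999).

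The TCam-2 test had the same size and the same pooled spread. With estimated correlations the calls of the pluripotency, G1/S, G2/M, MYC, cholesterol, immediate early and lysosome lists held.

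**Figure D3:**
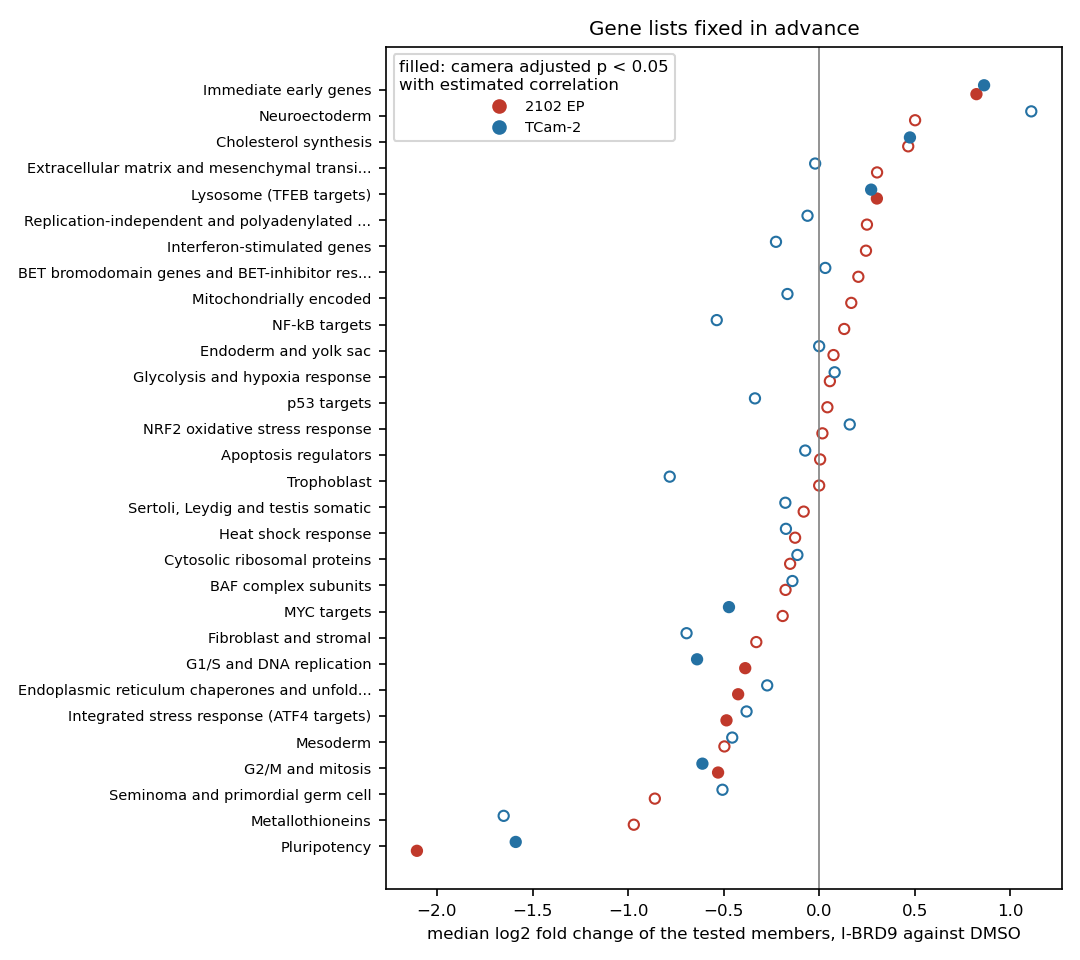
Median log2 fold change with I-BRD9 against DMSO (x axis) of the lists with at least 5 tested genes (y axis), 2102 EP in red and TCam-2 in blue, filled where the camera adjusted p with an estimated correlation was under 0.05. The pluripotency list has the lowest median in 2102 EP (−2.11), and the immediate early genes lie at 0.82 in 2102 EP and 0.86 in TCam-2.

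Many genes changed in the same direction in both lines. Of the genes that rose, 1289 did so in both, where independent sets would share 434.1 (Fisher's exact test across genes, odds ratio 8.84, 95% confidence interval 8.02 to 9.74). Of the genes that fell, 1328 did so in both, against 477.7 (odds ratio 7.79, 7.09 to 8.57). CDKN1C rose in both, from 31.6 ± 1.16 to 261.9 ± 19.0 CPM in 2102 EP, and NANOG, GDF3, UTF1 and VENTX fell in both. Across genes the log2 fold changes had a Pearson r of 0.389 and a Spearman rho of 0.468. With each line fitted alone r was 0.521, over the smaller set of genes that passed the low-count filter in both fits. Genes are not independent replicates, and the comparisons share no library.

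The response differed between the lines for 2043 genes by the test of the difference (edgeR, 13.1% of the genes tested), with a higher log2 fold change in TCam-2 for 921 and a lower one for 1122. CXCR4 changed in opposite directions, with a rise from 1.26 ± 0.553 to 4.50 ± 1.15 CPM in 2102 EP and the fall to 3.90 CPM in TCam-2 (difference −6.90 ± 0.33, edgeR adjusted p = 2.09e-13). VIM rose from 147.6 ± 4.33 CPM by 1.45 ± 0.09 on the log2 scale in 2102 EP and fell in TCam-2 (difference −3.85 ± 0.13, edgeR adjusted p = 2.57e-15). CDX2, which rose in 2102 EP, differed between the lines (−6.71 ± 0.62, edgeR adjusted p = 3.92e-09). CCND1, a cyclin gene chosen after its values were seen, rose by 0.69 in 2102 EP and fell by 0.69 in TCam-2 (difference −1.39 ± 0.11, edgeR adjusted p = 8.2e-09). In all, 273 genes were called in opposite directions, each also past the test of the difference, and 383 of the 2617 genes called in the same direction differed in size.

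The most positive differences, among called genes with at least 10 CPM in the highest group and the same symbols left out, belonged to FOXA3 (4.33), TOX2 (4.26), TRDN (4.22), LRCH4 (3.76) and ARHGAP4 (3.40). All 5 fell in 2102 EP, and all but TRDN (edgeR adjusted p = 0.0668) also rose in TCam-2. The rise was the larger part of the difference for TOX2 and ARHGAP4, and the fall for TRDN and LRCH4. FOXA3 had 1 count over the TCam-2 DMSO libraries and 0.36 CPM with I-BRD9 (ratio 8.81, counting interval 1.37 to 418). That interval is too wide to tell which part was larger for FOXA3. TOX2 fell in 2102 EP from 45.9 ± 7.48 to 19.1 ± 0.863 CPM and had 0.253 ± 0.338 and 2.27 ± 0.822 CPM in TCam-2. LRCH4 had reads shared with other genes. Among the most negative were those of DIO3 (−9.40), RSPH10B (−8.73), GFRA1 (−7.90) and CXCR4. FOXA3, DIO3 and GFRA1 had 1 to 3 counts in a group and RSPH10B none in a group, so that their fitted differences depend on the prior count and are not bounds. The RSPH10B call (edgeR adjusted p = 0.0163) was lost without 2102 EP I-BRD9 replicate 3 (0.0637) or TCam-2 I-BRD9 replicate 2 (0.0506) and with limma voom (0.0655), and GFRA1 (0.0016) without 2102 EP I-BRD9 replicate 3 (−6.40, 0.126).

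Among the pluripotency genes, 6 had a higher and 8 a lower log2 fold change in TCam-2 (9 and 9 adjusted over the list alone). NANOG (difference −2.17 ± 0.18), UTF1 (−1.93 ± 0.36), ZSCAN10 (−2.08 ± 0.22) and ESRG (−2.65 ± 0.12) fell more in TCam-2, and DNMT3L (2.08 ± 0.30), DNMT3B (1.23 ± 0.13), DPPA4 (1.07 ± 0.12) and L1TD1 (1.01 ± 0.11) fell more in 2102 EP. The list's median difference was −0.04, its mean 0.20 and its camera direction up (adjusted p = 0.203). Camera passed for 10 lists, 7 lower and 3 higher in TCam-2, and each was lost with an estimated correlation. In 4 of them, all lower, the adjusted p was under 0.005. They were the p53 targets (8 lower and BBC3 higher, 9 and 1 adjusted over the list alone; adjusted p = 0.0044, and adjusted p = 0.162 with an estimated correlation), the metallothioneins (4 lower, 6 adjusted over the list alone; 0.0027 and, with an estimated correlation, adjusted p = 0.242), the trophoblast genes (CDX2 lower, 3 adjusted over the list alone; 0.0044 and, with an estimated correlation, adjusted p = 0.162) and the mitochondrially encoded genes (5 lower, 7 adjusted over the list alone; 0.00106 and, with an estimated correlation, adjusted p = 0.242). Of the 9 trophoblast genes 4 had at most 3 counts in both 2102 EP groups, so that their response there could not be measured. Without such members, a test added after the results were seen, the list did not pass (camera adjusted p = 0.1099, median −0.077 in place of −0.620). CDKN1A, which rose in 2102 EP, had a difference of −1.19 ± 0.21 (edgeR adjusted p = 0.000271). The other 6 lay at the threshold, each with a camera adjusted p of 0.04995, and all were also lost with RLE scaling, with mitochondrially encoded genes left out, with a replicate or library-code block, and without members of at most 3 counts in both groups of a line (camera adjusted p 0.05076 to 0.1116). Lower in TCam-2 were the G1/S genes (CDC6 and CHAF1A lower, 7 adjusted over the list alone; adjusted p = 0.242 with an estimated correlation), the MYC targets (RRP9 lower, 5 adjusted over the list alone; adjusted p = 0.162 with an estimated correlation) and the extracellular matrix genes (9 lower and 4 higher, 10 and 4 adjusted over the list alone; adjusted p = 0.162 with an estimated correlation). Higher were the endoplasmic reticulum genes (XBP1 and HSPA5, the latter with shared reads; adjusted p = 0.162 with an estimated correlation), the cholesterol synthesis genes (6 higher and INSIG1 lower, 10 and 2 adjusted over the list alone; adjusted p = 0.242 with an estimated correlation) and the NRF2 targets (4 higher, 5 adjusted over the list alone; adjusted p = 0.242 with an estimated correlation). None of the other lists with at least 5 tested genes passed camera for the difference. Median, mean and test direction differed in sign for the seminoma, apoptosis, histone, endoderm, mesoderm and testis somatic genes.

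**Figure D4:**
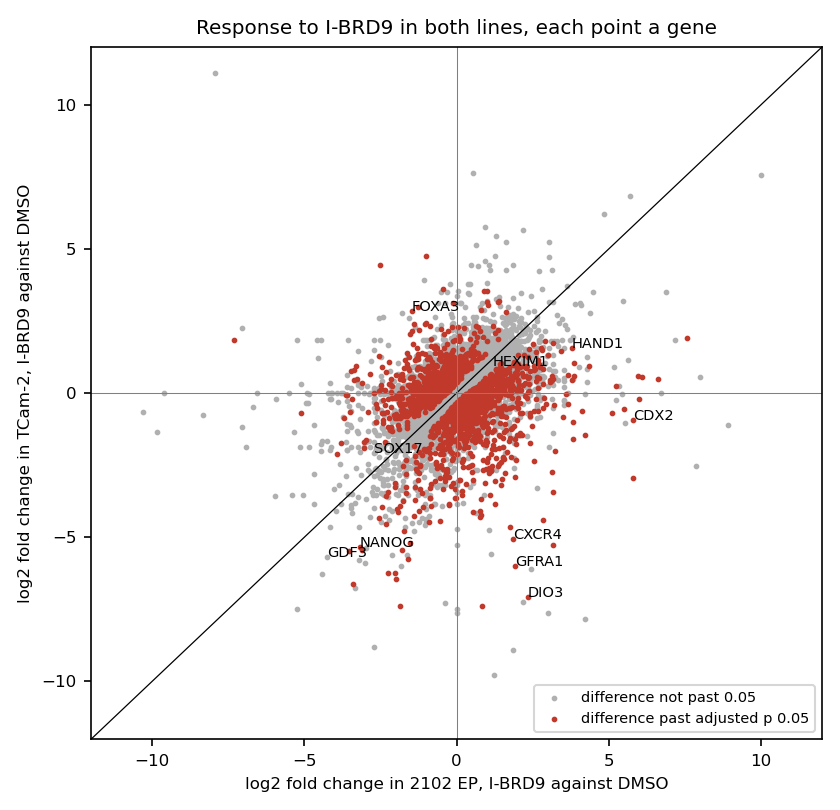
Log2 fold change with I-BRD9 against DMSO in 2102 EP (x axis) and TCam-2 (y axis) of the 15614 tested genes, red where the edgeR adjusted p of the difference between the lines was under 0.05, with a line of equal change. CXCR4, DIO3 and CDX2 lie far from the line, and HEXIM1 lies near it.

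With DMSO, the lines carried different marker genes. SOX2 was lower in TCam-2 (17.1 ± 2.28 CPM) than in 2102 EP (467.6 ± 21.1; log2 difference −4.78 ± 0.12, SE), and so were DNMT3B (−2.57 ± 0.09), LIN28A (−2.10 ± 0.08) and GDF3 (−6.52 ± 0.27). SOX17 had 2 counts over the 2102 EP libraries and a ratio of 2490 (95% counting interval 669 to 20000), and PRAME, a cancer-testis gene, also with 2 counts, one of 1920 (522 to 15600). KIT (4.36 ± 0.28), TFAP2C (3.05 ± 0.21), NANOG (1.58 ± 0.10), PDPN (1.56 ± 0.09) and POU5F1 (0.85 ± 0.08) were higher in TCam-2. All of these genes were named in advance and had edgeR adjusted p of at most 8.77e-07.

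Of the tested genes 4953 were higher and 4814 lower in TCam-2 with DMSO (edgeR, 62.6%). Of the 28 pluripotency genes 5 were higher and 21 lower (camera adjusted p = 9.35e-06), and all 9 trophoblast genes were higher (2.98e-05). Both calls held with an estimated correlation, and LEFTY2, a pluripotency gene with no count in TCam-2 with DMSO, was at least 2110-fold lower there. Of the 20 listed trophoblast genes 11 were not tested, and 4 of the 9 tested had at most 3 counts in both 2102 EP groups. These 4 passed the low-count filter through TCam-2, where they were high, so the filter set part of that result. In the same way 3 pluripotency genes had at most 3 counts in both TCam-2 groups. Of the seminoma and primordial germ cell genes, SOX17 and PRAME had so few in both 2102 EP groups, and LHX8 in both TCam-2 groups. Of 13 seminoma and primordial germ cell genes 9 were higher and 3 lower (camera adjusted p = 0.0315; adjusted p = 0.238 with an estimated correlation), and of 25 G1/S genes 3 were higher and 17 lower (camera adjusted p = 0.0309; adjusted p = 0.2 with an estimated correlation). None of the other lists with at least 5 tested genes passed camera, and median, mean and test direction differed in sign for the apoptosis, NF-kB, histone, glycolysis, neuroectoderm and fibroblast genes. Each line was grown in its own medium, so that line and medium cannot be told apart in this comparison.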

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

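The tests of these results were chosen before the results were seen, except 1 in the last paragraph. The effect of I-BRD9 differed between the lines for 2043 genes by edgeR's test of the difference, higher in TCam-2 for 921 and lower for 1122. When the libraries were regrouped, 2 of 100 drawn splits, the real one included, gave as many calls. The other had 6883 calls and swaps the treatment labels in 1 line, so that it tests the sum of the effects, a structure of the samples, and the highest count without it was 1150. The splits cannot exclude chance. Most mix I-BRD9 and DMSO libraries within a line, which puts the treatment effect into the spread and lowers their calls. The median over the other splits was 0 calls. Mixed groups limit the splits of the single comparisons in the same way. For the single comparisons 10 splits are too few for a share under 0.05: the real count was 5739 in 2102 EP (highest other 2), 4959 in TCam-2 (highest other 0) and 9767 between the lines with DMSO (highest other 0), and in each only the real split, 1 of 10, reached it.

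The differences could come from genes that 1 line does not transcribe, from shared reads, or from a response that depends on the cell type. Genes under 1 CPM in both groups of a line made up 4% of the genes past the test, against 13.4% of all tested genes. Genes with so few counts in a line can hardly pass, so a low share was likely in advance. The share shows only that most genes past the test reached 1 CPM in at least 1 group of each line. Genes with shared reads made up 9.3% of the genes past the test and 12.4% of all tested genes (ratio 0.74). This argues against shared reads as the source of most of the differences. For the genes past the test that do have shared reads, the ratio decides nothing. Cell type stays open as a hypothesis that was not tested, since line and medium cannot be separated with these groups.

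Among called genes with at least 10 CPM in the highest group, LINC, MIR and other symbols that the naming rule omits left out, the most positive differences in log2 fold change, TCam-2 minus 2102 EP, were those of FOXA3 (4.33), TOX2 (4.26), TRDN (4.22), LRCH4 (3.76) and ARHGAP4 (3.40). TRDN fell in 2102 EP from 25.2 to 2.52 CPM and ARHGAP4 rose in TCam-2 from 1.33 to 5.99 CPM. Among the most negative were those of DIO3 (−9.40), RSPH10B (−8.73), GFRA1 (−7.90) and CXCR4 (−6.90). RSPH10B was lost without 2102 EP I-BRD9 replicate 3 (edgeR adjusted p = 0.0637) or TCam-2 I-BRD9 replicate 2 (0.0506) and with limma voom (0.0655), and GFRA1 without 2102 EP I-BRD9 replicate 3 (0.126). The values of FOXA3, DIO3, RSPH10B and GFRA1 rest on groups with at most 3 counts and are not bounds.

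In 7 lists the effect was lower in TCam-2 by camera. In 4 of them the adjusted p was under 0.005, with a median difference of −0.324 for the p53 targets, −0.909 for the metallothioneins, −0.620 for the trophoblast genes and −0.384 for the mitochondrially encoded genes. None of these 4 calls held with an estimated correlation (adjusted p = 0.162, 0.242, 0.162 and 0.242 with an estimated correlation, in that order). The other 3 had an adjusted p of 0.04995, with a median difference of −0.261 for the G1/S genes, −0.216 for the MYC targets and −0.467 for the extracellular matrix genes (adjusted p = 0.242, 0.162 and 0.162 with an estimated correlation). At the same adjusted p, 3 lists had a higher effect in TCam-2, with a median difference of 0.177 for the endoplasmic reticulum genes, 0.263 for the cholesterol synthesis genes and 0.232 for the NRF2 targets (adjusted p = 0.162, 0.242 and 0.242 with an estimated correlation). These 6 calls lie at the threshold and were also lost with RLE scaling, with mitochondrially encoded genes left out and with a replicate or library-code block, and without list members that had at most 3 counts in both groups of a line, a test added after the results were seen. That test also ended the trophoblast call (camera adjusted p = 0.1099, median −0.077): 4 of its 9 genes had no measurable response in 2102 EP, so the list value of −0.620 does not show a difference of the lines.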

How the results depend on the processing

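Overlap of calls with each library left out, and list tests without members of at most 3 counts in both groups of a line, were chosen after the results were seen, and the other tests before. With an absolute log2 fold change of at least 1 the calls numbered 1076 up and 865 down in 2102 EP, 732 and 791 in TCam-2, 385 and 583 for the difference, and 2724 and 2497 between the lines with DMSO, fewer by construction. No other setting moved these counts by more than 1.5 times, and no call turned its direction. With a library left out, calls ranged from 2381 to 2706 up and 2339 to 2650 down in 2102 EP, 1934 to 2078 and 2211 to 2302 in TCam-2, 697 to 883 and 914 to 1155 for the difference, 4621 to 4709 and 4549 to 4636 with DMSO, and 1084 to 1269 and 1144 to 1359 for genes shared by the lines. Pearson r across genes moved from 0.389 to 0.521 with each line fitted alone. Those fits filter low counts anew, with 14131 genes tested in 2102 EP and 14038 in TCam-2 in place of 15614. The second r covers only genes tested in both, so the 2 values rest on different gene sets. How much of the move comes from the gene set was not tested. Of the named genes' results under other settings, 5761 stayed on their side of the threshold, 183 lost the call and 39 gained it. Of the list tests in each line and for the difference (the comparison with DMSO was not part of this tally) 522 stayed, 51 gained a call, 42 of them under fry, and 52 lost it. Of the losses 21 came with an estimated correlation, 30 were 6 lists of the difference at the threshold under 5 settings, and 1 was the trophoblast list of the difference without low-count members. Of the counts of list members in each line 119 moved by more than 1.5 times and 2057 did not.

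With a replicate block the calls were 2713 up and 2774 down in 2102 EP, 2224 and 2437 in TCam-2, 801 and 981 for the difference, 4855 and 4766 with DMSO, and 1209 and 1252 shared by the lines. Not every sample correlated best with its own number: same-numbered deviations correlated at −0.119, 0.096 and −0.079 in 2102 EP and 0.160, 0.034 and 0.127 in TCam-2. By library code, TCam-2 I-BRD9 replicate 1 pairs with DMSO replicate 2, and I-BRD9 replicate 2 with DMSO replicate 1 (correlations 0.018 and −0.078). A library-code block gave 2671 calls up and 2755 down in 2102 EP, and 2199 and 2408 in TCam-2. It gave 777 and 941 for the difference, and 4827 and 4750 with DMSO. Depth limits genes near 3 counts, and DESeq2 gave no adjusted p for 318 genes in the test of the difference.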

Other observations

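For the fall of the pluripotency genes, the tests of scaling and of short-lived transcripts were chosen after the result was seen, and the other tests in this part before it. Some single genes differed between the lines in their response, by edgeR's test of the difference (n = 3 per group), and they stand for no gene group. CHAC1, a glutathione-degrading enzyme gene, fell from 15.7 ± 1.33 to 8.58 ± 1.57 CPM in TCam-2 and more in 2102 EP (difference 2.83 ± 0.24), as did SLC7A11, the cystine transporter gene (2.26 ± 0.26). CASP8 fell from 83.1 ± 13.3 to 17.2 ± 3.33 CPM in TCam-2 and had 8.83 ± 0.305 and 10.3 ± 0.692 CPM in 2102 EP (difference −2.49 ± 0.22). FN1, the fibronectin gene, rose by 0.99 ± 0.17 in 2102 EP and fell by 1.06 ± 0.12 in TCam-2 on the log2 scale (difference −2.04 ± 0.21).

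ANGPTL4, outside the lists, fell in TCam-2 from 98.2 ± 7.02 to 3.86 ± 0.922 CPM and rose in 2102 EP by 1.74 ± 0.35 on the log2 scale (edgeR, difference −6.39 ± 0.42). WLS, also outside them and needed for WNT secretion, rose in both lines and more in 2102 EP (edgeR, difference −3.04 ± 0.20), from 2.64 ± 0.361 to 33.2 ± 3.49 CPM in 2102 EP and from 82.4 ± 6.95 to 125.8 ± 10.9 in TCam-2, with shared reads in part of the libraries.

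The pluripotency genes fell in both lines. The list's median nearest to 0 over the other scalings was −1.558. Upper-quartile scaling moved the median of all tested genes only from 0.002 to 0.043 in 2102 EP and from 0.007 to 0.038 in TCam-2. So small a shift could not have undone the fall, and the trial of scalings decides little. Scaling moves all genes of a library alike, so it is unlikely as the cause of a fall relative to the other genes. Reads shared with pseudogene copies are unlikely too, since the median of the 20 members with whole counts in all libraries was −1.367 in TCam-2 and −2.023 in 2102 EP. A loss of short-lived transcripts at large was looked for in the immediate early genes, whose smaller median was 0.823. These genes can be newly induced, so their rise does not show whether other short-lived transcripts were lost. That explanation stays open. A direct effect of the compound on the transcription of these genes may stand behind the fall, as may an indirect one. Neither hypothesis was tested with 1 compound, 1 dose and 1 time, and binding to bromodomains other than that of BRD9 was not measured.

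Neighbouring genes on chromosome 22 (17084954 to 17558149) were silent in TCam-2, with at most 3 counts over its 6 libraries. They are neighbours among protein-coding genes with at least 10 CPM on average in 2102 EP. Other genes in the interval were not part of the search, so the interval as a whole need not be silent. IL17RA, HDHD5, ADA2 and CECR2 had 3, 0, 3 and 1 counts over its 6 libraries and 16.4, 12.5, 15.9 and 51.2 CPM in 2102 EP. A chance neighbourhood of the 17 silent genes among 8001 is unlikely: none of 10000 random gene orders held such a run (permutation p = 1e-04, the smallest they can give), and the 16 genes silent in 2102 EP formed none. A lost DNA segment, which these 4 genes could mark, cannot be told apart from silenced transcription without data on DNA copies.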
